A study of Rattus norvegicus with 8 samples.

How the data were processed

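Expression was measured on 8 single-colour microarrays of inguinal white adipose tissue from male Fischer 344 rats, 4 for the control diet (CON) and 4 for the methionine-restricted diet (MR). Per the labels' protocols, total RNA was extracted with TriReagent and a column clean-up, made into digoxigenin-labelled cRNA and read by chemiluminescence. Diet and replicate number were taken from the sample labels, and each column of the value table carries the identifier of its own sample. The series description says that RNA was pooled, and the number of rats behind an array is not given in the sources used here. All p-values therefore measure only the spread between arrays, which may be technical.

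The deposited values are normalized signals, taken here to be on the log2 scale. The log base is not stated in the sources used here; base 2 was assumed from the range of 4.90 to 21.29, since another usual base would give signals far beyond what a scanner reads. All 8 columns have a median of 9.37 and nearly one distribution, with sorted values at most 0.00526 from their mean, the form that quantile normalization by the authors would leave. The values are not centred per probe. Background correction and any other step before deposit are not given in the sources used here, and the unit of the signal before the logarithm stays unknown. A second deposited table held scanner values of 12 arrays under codes that match no sample label. Its 60 columns of array values were not used, so detection, spot flags and signal over background were not assessed, and only its gene identifier for each probe was read. For arrays, their number limits the precision.

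Of the 26857 probes in the value table, 26800 carry a Celera transcript number and 57 a RefSeq accession. The accessions were matched without versions, and the Celera numbers as synonyms, to a RefSeq gene table of the rat assembly GRCr8, used for names alone. This named 34 probes by accession and 1 by synonym, or 35 probes of 34 genes; all other probes stay unnamed here. For that reason 4 unnamed probes at most, 2 higher and 2 lower in MR, are given by their Celera number.

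A probe was tested when its mean over the 8 arrays exceeded the 40th percentile of all probe means, 8.53 on the log2 scale, which left 16114 probes. This replaced the detection rule planned for scanner data. The planned wording could also be read as a level reached on 3 arrays of a diet, and that reading was run as an alternative. No further normalization was applied. MR was compared with CON by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method; an adjusted p under 0.05 counted as a call. Intervals are limma's 95% confidence intervals, and tests are two-sided. The planned tests of 37 gene lists with limma's camera needed 5 measured members. At most 1 member of any list had a named, tested probe, so 0 lists were tested, and no list medians are given.

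The rule for named genes was fixed before the data were examined. It took the 12 largest increases and 12 largest decreases among called probes with a gene symbol and no overlap between diets, up to 4 passing members (or 2 that did not pass) of each list, and a fixed set of genes of lipid synthesis, thermogenesis, adipokines, stress and inflammation. Among tested probes it yields Cebpb, Atf4 and Hbb-b1, all through the lists. The other genes are all those with a named, tested probe; they were chosen after their values were seen.

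The fit was tested on simulated data with the real probe means and spreads for the MR against CON comparison of 16114 probes, with 200 probes changed. With a true log2 change of 1 it recovered 0 of them, with 2 it recovered 108, and with 3 it recovered 147, all with the right sign. False calls numbered 0, 5 and 7, and a simulation without change gave 0 calls. Noise was drawn independently for each probe and array, without deviations shared between probes. In the real data 23.9% of tested probes had an unadjusted p under 0.05 in limma, so neither the recovery nor the false calls need carry over.

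Alternatives planned before the data were examined were no intensity filter, cyclic loess on the deposited values, eBayes without a trend or with robust estimation, array weights, replicate number as a block, leaving out each array, and a change of at least 1.5-fold. Alternatives added later were intensity filters on all 8 arrays or on 3 arrays of a diet, the mean level of one group of probes as a covariate, and an array set found in the data as a block and on its own. All 35 splits of the 8 arrays into 4 and 4 were refitted as well.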

Results

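Gene expression was measured in the inguinal white adipose tissue of male rats, a subcutaneous fat depot of the groin, after 20 months on a control or a methionine-restricted diet. The animals were of the inbred Fischer 344 strain and started the diets at 32 days of age. Methionine is an essential, sulfur-containing amino acid; it made up 0.86% of the CON diet and 0.172% of the MR diet. Each diet was represented by 4 arrays of pooled RNA. Each of the 8 arrays had a median signal of 9.37 on the log2 scale, and 16114 of 26857 probes lay above the intensity filter.

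The comparison of MR with CON asked which transcripts of the depot differed after long-term methionine restriction. At a limma adjusted p under 0.05, 129 probes were higher and 216 lower in MR, together 2.14% of those tested. Of the called probes, 128 of the higher and 210 of the lower ones differed by at least 2-fold. Their median log2 change was 2.14 among the higher and -1.73 among the lower ones. These sizes follow in part from the selection, since the simulation recovered 0 of 200 probes with a true log2 change of 1. Over all tested probes the median log2 change was -0.059, with 62 over 8-fold higher and 12 over 8-fold lower. Among called probes, changes of at least 8-fold were seen in 32 of the higher and 3 of the lower ones. Of those 32, 25 belong to a set of 87 probes, 28 of them called, in which CON replicate 2 was high together with all MR arrays, over 2 log2 units above the other CON arrays; 7 lie outside it. None of the called probes has a gene symbol here, so the genes behind these 345 calls are not named. At an unadjusted p under 0.05 there were 3849 probes, or 23.9% of those tested. In 974 probes every MR array lay above every CON array, and in 1408 every MR array lay below. Together these are 14.8% of the tested probes, where exchangeable arrays would give 2.86% on average. Probes vary together, so a single split can lie far from that average, and the share was not computed for other splits. Of the called probes, 342 had no overlap between the diets.

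The counts depended on the settings and on single arrays. They were 50 higher and 97 lower without the intensity filter, 27 and 76 without a trend, and 644 and 785 with array weights, and cyclic loess gave 131 lower. With the mean level of 45 probes bright in CON replicates 1 and 3 and MR replicate 2 as a covariate they were 12 and 8, and with the set of CON replicates 3 and 4 and MR replicate 1 as a block 11 and 5. Within the other 5 arrays of that block limma called 0, with 2358 at an unadjusted p under 0.05. The 3 arrays of the set hold 1 MR array, so no count of calls is given for them. These covariate and array-set fits were chosen after seeing the data. Without CON replicates 1, 2, 3 and 4 in turn, 11, 637, 2 and 11 probes were higher and 8, 700, 0 and 14 lower in MR. Without MR replicates 1, 2, 3 and 4 in turn, 233, 0, 7 and 1 were higher and 283, 0, 3 and 1 lower; the empty limma result without MR replicate 2 went with 3250 probes at an unadjusted p under 0.05.

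**Figure D1:**
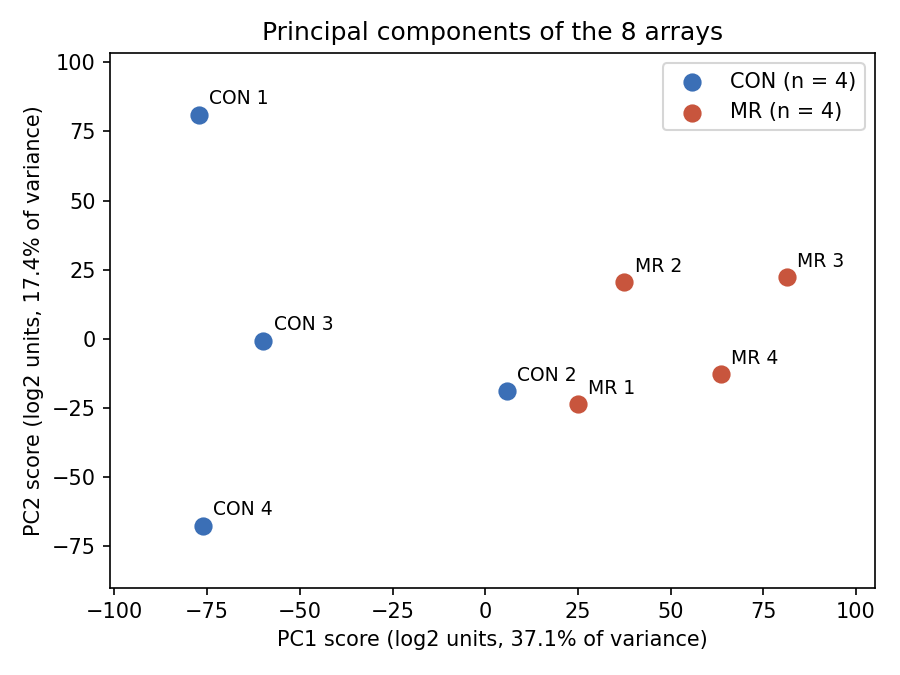
Principal components of the 8 arrays over the 16114 tested probes; each point is 1 array, and the axes give scores in log2 units with the share of variance. The MR arrays lie at 24.9 to 81.4 on the first component, CON replicate 2 at 5.86 and the other CON arrays at -77.3 to -59.8.

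The 2 largest increases and the 2 largest decreases among called probes without overlap, all in unnamed transcripts, were of 9.45-fold or more. The transcript rCG24645 had a log2 signal of 8.997 ± 3.53 in CON and 16.97 ± 0.23 in MR (SD, n = 4), a log2 change of 7.97 (SE 1.36, limma adjusted p = 0.0302). Its level was 6.96 to 7.39 in CON replicates 1, 3 and 4 but 14.28 in CON replicate 2, and without that array the change was 9.73. The transcript rCG60412 had 10.44 ± 2.94 in CON and 16.73 ± 0.04 in MR, a change of 6.29 (SE 1.13, limma adjusted p = 0.0341). CON replicate 2 again lay highest of its group at 14.70, against 8.20 to 10.06 in the others, and the change without it was 7.71.

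Among the decreases, rCG32669 fell from 12.55 ± 0.19 in CON to 8.93 ± 0.98 in MR, a log2 change of -3.62 (SE 0.46, limma adjusted p = 0.0152). The transcript rCG37339 fell from 12.40 ± 1.17 to 9.16 ± 0.38, a change of -3.24 (SE 0.53, limma adjusted p = 0.0266). In CON replicate 2 its level was 10.69, against 12.71 to 13.32 in the other CON arrays, and the change without that array was -3.81. The increases had CON arrays, and the decreases MR arrays, near or below the filter level of 8.53, so the sizes of all 4 changes rest on dim signals whose background was not assessed. With 1 array left out at a time, the calls held in 2 of 8 fits for rCG24645, rCG60412 and rCG37339, those without CON replicate 2 and without MR replicate 1. For rCG32669 the call held in 6 of 8, and was lost without CON replicate 3 (limma adjusted p = 0.079) and without MR replicate 2 (0.0542). In the other 3 transcripts, the limma adjusted p of the fits that lost the call ranged from 0.0684 to 0.112. Over all refits with more than 1 array per diet, the call held in 7 of 18 for rCG24645, 6 of 18 for rCG60412, 14 of 18 for rCG32669 and 9 of 19 for rCG37339. Without an intensity trend the calls of rCG24645 and rCG60412 were lost (limma adjusted p = 0.0528 and 0.0552), and with robust estimation that of rCG60412 (0.0543).

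**Figure D2:**
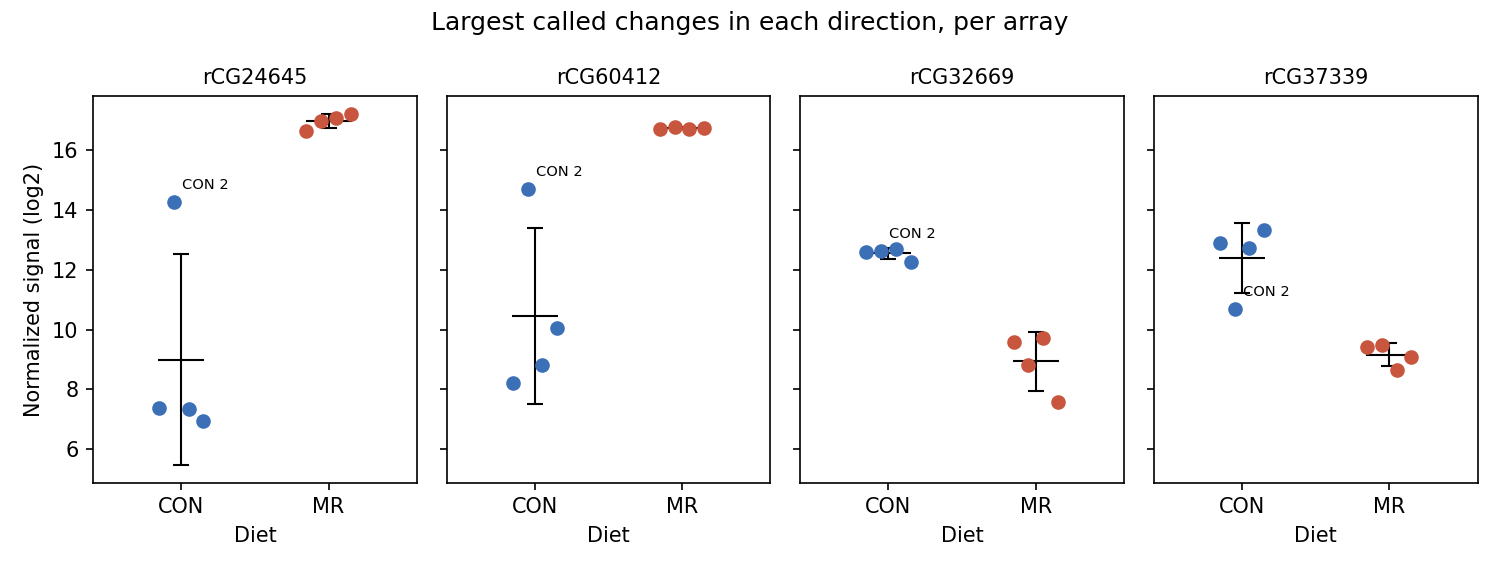
Normalized log2 signal of the 4 transcripts in each array, with the mean (dash) and SD (bar) of each diet, n = 4. The MR arrays lie at 16.65 to 17.19 for rCG24645, above CON replicate 2 at 14.28 and the other CON arrays at 6.96 to 7.39.

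Of the 12 genes with a named, tested probe, 0 passed the limma test over all probes, and 4 had an unadjusted p under 0.05. Rtn3, which encodes a reticulon protein of the endoplasmic reticulum, had the smallest p. Its log2 signal was 9.01 ± 0.48 in CON and 10.85 ± 0.80 in MR (SD, n = 4), a change of 1.84 (95% confidence interval 0.82 to 2.86, limma adjusted p = 0.0622), with all 4 MR arrays above every CON array. Adjusted over these 12 genes alone, a set chosen after the values were seen, its p was 0.0276. Kcnip2, a potassium channel interacting protein, was at 11.61 ± 0.67 in CON and 12.85 ± 0.56 in MR (limma adjusted p = 0.0991), and 3 of 4 MR arrays exceeded every CON array. Another Kcnip2 probe, below the filter, differed by 0.22 when fitted without it. Ramp2, the adrenomedullin co-receptor subunit found in endothelium, was at 15.56 ± 0.67 and 14.62 ± 0.47, a change of -0.94 (limma adjusted p = 0.147). Itgae, the integrin alpha E chain of tissue-resident lymphocytes, was at 11.31 ± 0.65 and 12.11 ± 0.28 (limma adjusted p = 0.194); CON replicate 4 lay apart at 10.35, and the change of 0.79 became 0.47 without it.

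Of the 37 gene lists fixed beforehand, 3 had a tested member, 1 each, and the other 34 had 0. The adipocyte transcription factor Cebpb differed by -0.15 (95% confidence interval -0.68 to 0.38), with CON at 16.42 ± 0.36 and MR at 16.27 ± 0.24. Atf4, the transcription factor of the amino acid stress response, differed by -0.21 (interval -0.64 to 0.21), from 16.17 ± 0.20 to 15.96 ± 0.10. With 1 array left out, Cebpb ranged from -0.32 (without CON replicate 4) to -0.04 (without CON replicate 2). For both genes the limma intervals exclude a change of 2-fold, also in each of the 8 fits with 1 array left out. These intervals cover the spread between arrays of pooled RNA, not that between rats. The red blood cell gene Hbb-b1, a haemoglobin beta chain, was very bright in both diets, at 20.08 ± 0.60 in CON and 19.38 ± 0.15 in MR, a difference of -0.70 (interval -1.44 to 0.04, limma adjusted p = 0.231). Among the other 5 genes, Six3, Tpra1, Lypd4 and Arhgef1 had differences of 0.79, 0.43, 0.53 and 0.52, and Rnase3 one of -0.65; their limma adjusted p ranged from 0.244 to 0.636. Single arrays moved these estimates: Arhgef1 was 0.08 without MR replicate 3 and 1.04 without MR replicate 1, Tpra1 was 0.15 without CON replicate 1, and Lypd4 was 0.30 without MR replicate 4 and 0.83 without MR replicate 3. The extracellular matrix gene Mmp2 lay below the filter, as did the other probes of the 23 with a symbol that were not tested. Without the filter, limma called 0 of these 23, and 3 had an unadjusted p under 0.05.

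**Figure D3:**
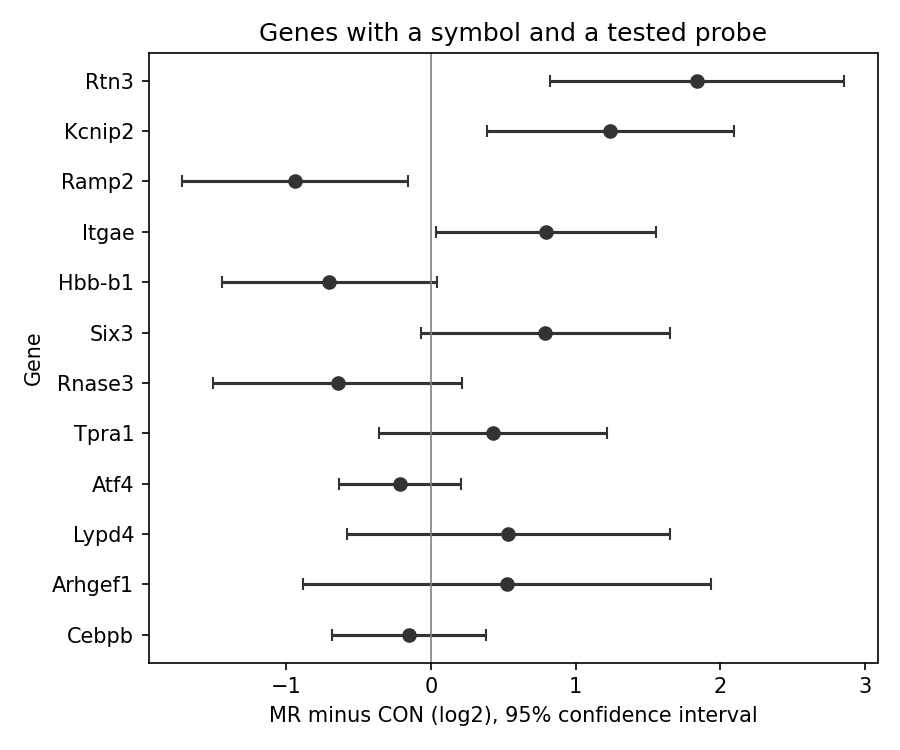
Difference between MR and CON (log2) of the 12 genes with a symbol and a tested probe; points are limma estimates and bars their 95% confidence intervals, from 4 arrays per diet. The estimates run from -0.94 for Ramp2 to 1.84 for Rtn3.

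Array similarity, measured by correlation across the tested probes, which are not independent replicates, was higher within than between the diets at the median, with overlap between single pairs. Pearson's r had a median of 0.910 over the 6 pairs of CON arrays, 0.924 over the 6 pairs of MR arrays and 0.877 over the 16 mixed pairs. The highest of all pairs was the mixed pair of CON replicate 2 and MR replicate 1, at 0.945. Without CON replicate 2 pairs still overlapped: CON replicate 3 and MR replicate 1 had 0.911, and CON replicates 1 and 4 had 0.881.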

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

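Every test in this part was chosen after the pattern it bears on was seen, and its bounds were set after its result was seen or partly seen, except the test of a processing batch for the probes high in CON replicates 1 and 3 and MR replicate 2. Chance sets about 1 in 20 groups of arrays apart by the measure used in the next paragraph, and 38 groups were examined.

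In 3 of these groups 1 array stood far from the other 3, as measured by its gap to the nearest array over the range of the group. For Itgae in CON the ratio was 0.867, with CON replicate 4 at 10.35 and the others at 11.56 to 11.75. For rCG24645 in CON it was 0.941, with CON replicate 2 at 14.28 and the others at 6.96 to 7.39. For the number of probes in which 1 array alone lay over 2 log2 units from all others it was 0.918 in CON: CON replicate 1 had 655 such probes, 407 of them high and 248 low, and the other CON arrays 18 to 70.

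The diet calls were set against all 35 splits of the 8 arrays into 4 and 4. Only 1 split, the diets themselves, gave as many as 345 called probes; the highest of the other splits gave 0 in limma, with at most 2636 probes at an unadjusted p under 0.05 against 3849 for the diets. The diets alone reached this count, a share of 0.0286, which is the smallest that 35 splits allow. Each other split mixes the diets, and the test was chosen after the count was seen. Chance is therefore argued against, but not excluded, as the origin of the count among these 8 arrays. They may be technical repeats, and the splits do not bear on differences between rats.

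In 4 probes all MR arrays were parted from all CON arrays by being high. CON replicate 2 lay with the MR arrays on probes higher in MR, but between the diets on the first component (5.86). It was high together with all 4 MR arrays in 87 probes (28 of them called) and low with them in 1. There it lay over 2 log2 units from CON replicates 1, 3 and 4. Its place was read on the 250 clearest probes in each direction, chosen without it, from 0 at the mean of the other CON arrays to 1 at the MR mean; its median was 0.861 on probes higher in MR (left-out MR arrays 0.823 to 1.13, other CON arrays up to 0.161). A swap with an MR array is argued against, because the lowest median place of any left-out MR array was 0.776 and the highest of the other CON arrays 0.278. A wrong diet label on CON replicate 2 alone stays open. On probes lower in MR its place was 0.536, below every MR array (0.776 to 1.12) but above 0.491, the 95% limit for a further MR array. That limit treats the places of the left-out MR arrays as independent, though they were read against shared arrays, so its level is approximate. Handling or RNA shared with MR replicate 1 stays open too: their deviations correlated at 0.375 over probes without a diet difference, but this pair, the most alike over all probes, had prompted the test, and with MR replicates 2, 3 and 4 the values were -0.0231, 0.123 and 0.0770; a biological difference among CON rats was not tested.

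A set of 45 probes was over 2 log2 units higher in CON replicates 1 and 3 and MR replicate 2 than in the other 5 arrays, while 0 probes were as far below, with means of 14.68, 14.63 and 13.39 against 8.50 to 9.27; 0 of them were called for diet by limma. For this array set, 4.53% of the other tested probes, or 728, had an unadjusted p under 0.05 in limma. This cannot decide on a processing batch that moved many probes, because 5% need not be the level without a batch here. Splits with 2 arrays of each diet on both sides gave 148 to 601 such probes, though they part 4 arrays from 4. At the adjusted threshold limma called 8 of the tested probes outside the 45 for this array set, so a batch that moved few probes is not excluded either. RNA of another tissue in different shares would put all probes on this side, as found, but stays undecided. A single source would hold the log2 ratio of 2 arrays constant over the 45 probes. The ratio of CON replicate 1 to 3 varied with an SD of 1.19, yet other bright probes gave 0.883. That of CON replicate 3 to MR replicate 2 varied less, with an SD of 0.672, and has no value from other bright probes beside it. No biological explanation was tested.

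In 14 probes CON replicates 3 and 4 and MR replicate 1 lay over 2 log2 units from the other 5 arrays. In limma, 5.52% of tested probes, or 890, had an unadjusted p under 0.05 for this array set. Again this cannot decide on a processing batch that moved many probes, since splits with 2 arrays of each diet on both sides gave 148 to 601. At the adjusted threshold limma called 17 probes for the set, 6 high and 11 low, so a batch that moved few probes is not excluded either. RNA of 1 other source in some arrays is argued against, because the 14 probes went both ways, 6 high and 8 low in these arrays. Any of the other 55 sets of 3 arrays held at most 1 in its rarer direction, against 6 here. That comparison adds no support, since the set was found through the same gaps. The cause was not tested further, and no biological explanation was tested.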

How the results depend on the processing

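Array-set, covariate and per-array filter settings were chosen after seeing the data; the rest were planned. Among fits on all 8 arrays, within 1.5 times of the 129 higher and 216 lower probes were the counts with robust estimation and both per-array filters (145 and 257 on 3 arrays of a diet), and the higher count under cyclic loess. A 1.5-fold minimum could remove no call, since the smallest called log2 changes were 0.964 and -0.902. Counts of higher and lower probes were 50 and 97 without the intensity filter, 27 and 76 without a trend, and 644 and 785 with array weights; under cyclic loess the lower count was 131. The replicate block gave 0 and 0, with 3465 probes at an unadjusted p under 0.05 in limma. Deviations of same-numbered arrays correlated at -0.0850, -0.254, -0.0803 and 0.104, and 2 of 8 arrays were closest to their own number. The numbers were therefore not treated as pairs. With the mean level of the 45 probes high in CON replicates 1 and 3 and MR replicate 2 as a covariate, 12 and 8 were called; with CON replicates 3 and 4 and MR replicate 1 as a block, 11 and 5. Within that set of 3 arrays, where the lone MR array is assumed to vary like CON and the spread comes from 2 CON arrays alone, 439 and 325 were called; within the other 5, 0 and 0, with 2358 at an unadjusted p under 0.05. Leaving out 1 array at a time gave 0 to 637 higher and 0 to 700 lower probes: 637 and 700 without CON replicate 2, when 342 of the 345 calls were kept, 0 and 0 without MR replicate 2, and, within 1.5 times, 283 lower without MR replicate 1. Fits with a block, a covariate or fewer arrays have fewer degrees of freedom; otherwise the cause was not tested. Leaving aside the fit with a lone MR array, of 298 refitted values for the 16 named genes and transcripts, 259 kept direction and side of the threshold, 37, all of the 4 unnamed transcripts, lost a call (all 4 under the replicate block, limma adjusted p 0.0837 to 0.0975), and 2 gained one with array weights: Rtn3 (0.0227, range 0.0227 to 0.24) and Ramp2 (0.0443, range to 0.368). Against the lone MR array the sign turned for Arhgef1 (-0.41) and Cebpb (0.022), which is the place of 1 array. Median scaling moves nothing, since all medians are equal, and the authors' values are used throughout. Background correction, detection by signal over noise, array batch and the gene list alternatives were not run, for want of values tied to the samples or of named members. Signal over background was not assessed.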

Other observations

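The test in this part was chosen after its result was seen. Where several probes share an identifier, their diet differences can be set against each other, to see whether a difference belongs to the transcript or to the single spot. Over 295 pairs of tested probes from 268 identifiers, the log2 changes correlated at 0.427 (Spearman 0.436). Shuffling the partners 10000 times gave at most 0.218, with a permutation p of 1e-04, the smallest that this number allows. In the 102 pairs with both probes above a mean of 12 the correlation was 0.754, and in the 7 pairs that held a called probe both probes differed in the same direction, though both were called in 1 pair alone. This is consistent with diet differences that follow the transcript rather than the spot, at 0.427 over all pairs. It does not separate diet from anything else that differed between the arrays, and pairs of probes are not independent replicates.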
